A study of Parafrankia sp. EAN1pec and Parafrankia sp. EUN1f and Pseudofrankia inefficax with 18 samples.

How the data were processed

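RNA was extracted with an RNeasy kit, stable bacterial RNA was removed with a MICROBExpress kit and Illumina libraries were made, per the labels' protocols. The 18 libraries come from strains EAN1pec, EUN1f and EuI1c. According to the series' design text, reads were mapped to the genome of each strain with the CLC genomics software. Its version, the mapping settings, the genome builds and the strand setting of the counting are not given in the sources used here. Each deposited table holds 1 library, with a row per gene.

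Per the file headers, the deposited tables give the total and the uniquely mapped read count of each gene, and these counts are whole numbers that are not normalised. Per the file headers, the authors also give RPKM, computed from the total count, the gene length and the mapped reads of the library. The expression value column repeats the RPKM. Gene lengths are multiples of 3 and were taken as coding length. The tables list 7191 genes for EAN1pec, 7417 for EUN1f and 7083 for EuI1c. The total of mapped reads behind each RPKM was computed from the RPKM, count and length, and came to 6328924 to 139734899 per library.

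Samples were grouped by their labels into nitrogen-replete and nitrogen-deficient cultures of each strain, with batches 1, 3 and 4 as replicates. The gene identifiers of the 4 batch 1 files labelled EUN1f or EuI1c belong to the other strain. By a rule fixed before the data were examined, these files were left out of the main comparisons, which leaves 2 libraries against 2 in EUN1f and EuI1c and 3 against 3 in EAN1pec. Grouping them by the genes they list was an alternative fixed at the same time. Samples of each group differed from each other by more than sampling noise (chi-square of at least 3.60 per degree of freedom), so each was counted as a replicate. Nothing in the labels says that the batches were separate cultures, so p-values measure the spread between these libraries, which may be technical in part.

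Within each strain, total counts were tested with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, with TMM factors, its default filter on low counts (filterByExpr, minimum count 10 and minimum total 15) and Benjamini-Hochberg adjustment at 0.05. CPM values were computed here from the deposited counts, relative to the reads in tested genes scaled by the TMM factor. The SE of a log2 fold change is its size divided by the square root of the test statistic. Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), other scaling factors, other filters, uniquely mapped reads, a minimum log2 fold change of 1, a block for the batch number and leaving out each library in turn. Fold changes per batch used log2 CPM with a prior count of 2, for genes with a mean of at least 10 reads. Summaries were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Ratios of read rates pool the reads of a group over its total reads in genes, with exact 95% binomial intervals. Intervals and floors cover counting error alone.

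Named genes follow a rule fixed before the data were examined. As the files give no product names, it names at most 2 identifiers per direction and strain, those with the largest change among genes that passed or, where too few passed, those with the smallest p. The gene beside Franean1_6204 was added after its values were seen. The 25 gene lists fixed beforehand, among them nitrogenase and ammonium assimilation, their tests and the test of strain differences gene by gene were not run, because they need gene symbols or product names.

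The batch number comes from the sample labels, which call it a batch, and pairs the replete and deficient library of a batch. Deviations from the group means correlated at 0.29, 0.091 and 0.29 between same-batch libraries of EAN1pec in batches 1, 3 and 4, at 0.12 in EUN1f and at 0.23 in EuI1c. Where batch 1 was grouped by the genes listed, the values for batches 1, 3 and 4 were 0.55, 0.28 and -0.026 in EUN1f and 0.60, 0.46 and -0.092 in EuI1c, so the batch 4 pairs did not deviate together there. On simulated counts in which 100 genes changed 4-fold and 100 changed 16-fold, the unblocked test recovered 60% and 96% in EAN1pec (1006 genes tested). It recovered 16% and 81% in EUN1f with 4 libraries (2214 genes) and 20% and 88% in EuI1c with 4 libraries (4116 genes). With batch 1 grouped by the genes listed it recovered 69% and 99% in EUN1f (2693 genes) and 44% and 100% in EuI1c (5177 genes). The simulated counts were drawn independently around a common mean profile, with no structure of batches or libraries. Changes were placed only in genes that had passed the filter. Recovery in the real libraries may therefore be lower. A count of 0 reads allows a rate of up to 273 CPM of all reads in genes in the shallowest library and 2.43 CPM in the deepest, at 3 reads.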

Results

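Transcripts were counted in 3 strains that the labels call Frankia, actinobacteria of the root nodules of actinorhizal plants. The labels name their organisms as Parafrankia sp. EAN1pec, Parafrankia sp. EUN1f and, for strain EuI1c, Pseudofrankia inefficax, which is known as an ineffective symbiont that does not fix nitrogen. The strains were each cultured for 2 days at 28 °C in MP medium, either nitrogen-replete (labelled NH4) or nitrogen-deficient (labelled N2). Each strain and condition was sampled in batches 1, 3 and 4, which gives 18 libraries in 6 groups of 3. For every protein-coding gene the tables hold a read count and an RPKM value (reads scaled to gene length and to the mapped reads of the library). They identify genes by locus identifier and coordinates and pair them with no gene symbol or product, so genes are named here by identifier and position. The genome build is not given in the sources used here.

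Reads in listed genes ranged from 10996 to 1233058 per library. In EAN1pec, batches 1, 3 and 4 held 76668, 23205 and 155928 such reads under nitrogen-replete conditions and 160878, 10996 and 19916 under nitrogen-deficient conditions. The 2 batches of EUN1f that list EUN1f genes, batches 3 and 4, held 106066 and 83916 nitrogen-replete and 137655 and 222936 nitrogen-deficient reads. Batches 3 and 4 of EuI1c held 240433 and 64785 nitrogen-replete and 151156 and 264745 nitrogen-deficient reads. The 4 batch 1 libraries labelled EUN1f or EuI1c list the genes of the other strain. The replete and deficient libraries labelled EUN1f, with 471480 and 455333 reads, list the 7083 genes of EuI1c, and those labelled EuI1c, with 1233058 and 734719 reads, list the 7417 genes of EUN1f. These 4 libraries were left out of the gene tests within EUN1f and EuI1c, except where batch 1 is said to be grouped by the genes it lists. The share of mapped reads in listed genes was summarised by label and includes them.

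The first comparison asked which transcripts of EAN1pec differ in abundance between nitrogen-deficient and nitrogen-replete cultures. Of 7191 genes listed, 940 had enough reads to be tested. A single gene, Franean1_6204, passed as higher in deficient cultures, and none passed as lower. Franean1_6204 lies on the minus strand of the chromosome at 7537420 to 7538703, with a coding length of 1284 bases. Its normalised read count was 140 ± 23.9 CPM (read counts scaled to a common library total, SD, n = 3) in replete and 2272 ± 283 CPM (SD, n = 3) in deficient cultures. The log2 fold change was 3.95 (SE 0.46, adjusted p = 0.00207, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 940 genes). The gene was higher in 3 of 3 batches, by 3.77, 3.80 and 3.48 on the log2 scale in batches 1, 3 and 4. The reads behind these values were 8, 2 and 16 in the replete libraries of batches 1, 3 and 4 and 276, 18 and 30 in the deficient libraries.

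The gene next to Franean1_6204, at 7537085 to 7537423 on the same strand, overlaps its downstream end and had 223 ± 245 CPM in replete and 881 ± 213 CPM in deficient cultures (SD, n = 3). Its log2 fold change of 2.37 (SE 0.75) did not pass the test (edgeR adjusted p = 0.996), though limma-voom called it (log2 fold change 3.37, adjusted p = 0.0256), and it was higher in 3 of 3 batches. Franean1_1769, at 2125850 to 2126920 on the minus strand, had the second smallest p. It measured 202 ± 219 CPM in replete and 1644 ± 1026 CPM in deficient cultures (SD, n = 3), a log2 fold change of 3.44 (SE 0.78) with an adjusted p of 0.449 in edgeR and 0.00479 in DESeq2, which called it. Batch 1 held 298 of its 321 deficient reads, and its log2 fold change was 2.63 without the deficient batch 1 library and 4.23 without the replete batch 3 library. Of the genes lower in deficient cultures, Franean1_6051 (7362625 to 7363818, minus strand) had the smallest p, with 12573 ± 1911 CPM against 8270 ± 769 CPM (SD, n = 3). Its log2 fold change was -0.60 (SE 0.22), or -0.37 without the replete batch 1 library. Franean1_4642 (5535509 to 5540398, minus strand) had 1031 ± 279 CPM in replete and 357 ± 174 CPM in deficient cultures (SD, n = 3), a log2 fold change of -1.32 (SE 0.52), or -1.97 without the deficient batch 1 library. Neither passed (edgeR adjusted p = 0.996 for both).

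Among the 940 tested EAN1pec genes, 18 had an unadjusted p under 0.05 in the unblocked edgeR test, where chance alone gives 47. That count was 39 with the batch number as a block and 72 with limma-voom, so its place under or over chance depended on the method. In all 3 batches 253 genes (26.9%) moved the same way, where chance gives 25%. With the batch number as a block, 4 EAN1pec genes passed, of which 2 were higher and 2 lower in deficient cultures. The 2 higher genes were Franean1_6204 and Franean1_1769 (edgeR adjusted p = 0.000561 for the latter). The 2 lower genes had log2 fold changes of -1.39 and -1.72 with the block (edgeR adjusted p = 0.0189 and 0.0277). With reads summed over runs of neighbouring genes, a setting chosen after seeing the data, the same block called 1 run, that of Franean1_6204, and Franean1_1769 had an edgeR adjusted p of 0.123. Without the replete batch 3 library, Franean1_6204 kept a log2 fold change of 3.74 but had an adjusted p of 0.0595 in edgeR, and no gene passed. Of the strain's 20 most-read genes, 15 were shared by both conditions, and the 25 genes in either list differed by at most 0.93 on the log2 scale.

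**Figure D1:**
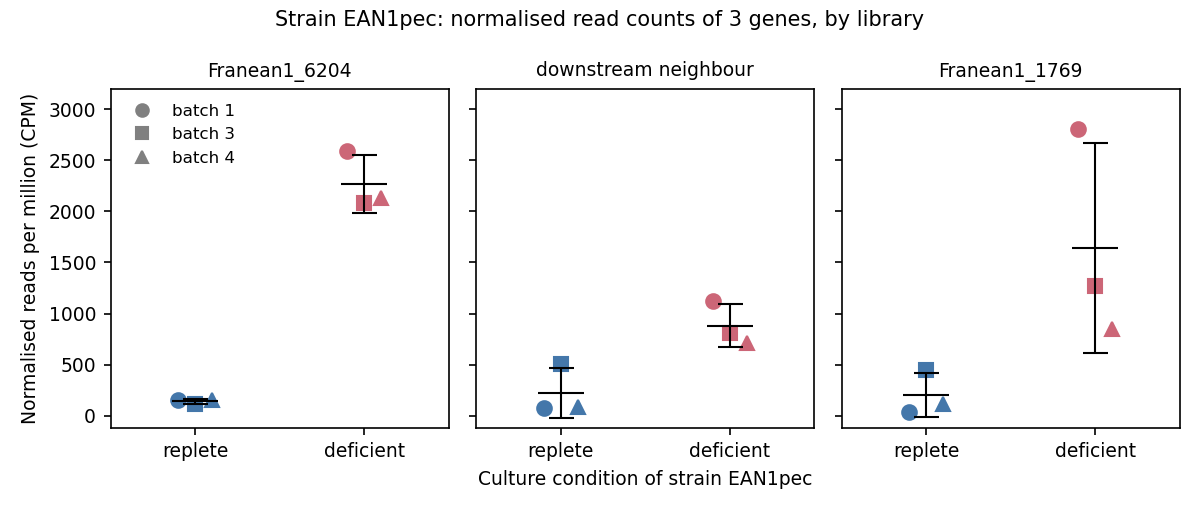
Normalised read counts (CPM, vertical axis, linear) of Franean1_6204, the gene that overlaps its downstream end, and Franean1_1769 in EAN1pec, with replete libraries in blue and deficient libraries in red. Each symbol is 1 library (circle, batch 1; square, batch 3; triangle, batch 4), and black bars give the mean and SD of 3 libraries. For Franean1_6204 every deficient library lies above every replete library, with means of 2272 and 140 CPM.

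The second comparison asked the same of EUN1f, with 2 replete and 2 deficient libraries. No gene passed the test among 2107 tested (edgeR quasi-likelihood, smallest adjusted p = 0.410), and 85 genes had an unadjusted p under 0.05, where chance gives 105. DESeq2 and limma-voom also called 0 genes. FrEUN1f_6880 came nearest. This gene of 138 bases at 8216084 to 8216221 (minus strand of the sequence the files call unknown) measured 240 ± 18.7 CPM in replete and 12.6 ± 7.28 CPM in deficient cultures (SD, n = 2), a log2 fold change of -4.31 (SE 0.96). It was lower in both batches, with 19 and 19 replete reads against 2 and 2 deficient reads. Its pooled read rate in deficient cultures was 0.0555 times that in replete cultures (exact 95% interval 0.0144 to 0.154). With the batch number as a block, FrEUN1f_6880 was the 1 gene that passed (edgeR adjusted p = 0.0288), and 0 runs of neighbouring genes passed with that block when their reads were summed, a setting chosen after seeing the data.

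FrEUN1f_0041 (47587 to 47892, plus strand of the same sequence) measured 363 ± 277 CPM in replete and 48.0 ± 20.2 CPM in deficient cultures (SD, n = 2), a log2 fold change of -2.95 (SE 0.84). FrEUN1f_5253 (6382812 to 6384863, plus strand of that sequence) was at 85.2 ± 86.7 CPM in replete and 705 ± 733 CPM in deficient cultures (SD, n = 2), a log2 fold change of 3.07 (SE 0.92). FrEUN1f_7399, on Contig463 at 628857 to 629816 (plus strand), had 3 reads in the replete and 73 in the deficient libraries, a ratio of read rates of 12.8 (exact 95% interval 4.22 to 63.6). None of these 3 genes passed (edgeR adjusted p = 0.992 for each). Several values moved with single libraries. The log2 fold change of FrEUN1f_5253 ranged from 1.14 (without the deficient batch 4 library) to 4.53 (without the replete batch 4 library). That of FrEUN1f_0041 ranged from -3.72 (without the replete batch 3 library) to -2.02 (without the replete batch 4 library), and that of FrEUN1f_6880 from -5.12 (without the deficient batch 3 library) to -3.66 (without the deficient batch 4 library). With batch 1 grouped by the genes it lists, the log2 fold changes were smaller in size, at -2.41 for FrEUN1f_6880, -1.89 for FrEUN1f_0041, 1.44 for FrEUN1f_5253 and 1.88 for FrEUN1f_7399. In that grouping single batch 1 libraries set these sizes: without the deficient one FrEUN1f_6880 was at -4.96 and FrEUN1f_0041 at -2.95, and without the replete one FrEUN1f_5253 was at 3.00 and FrEUN1f_7399 at 2.87.

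The 2 batches of EUN1f differed in how far their libraries stood apart. Counts of the 2 batch 3 libraries differed by a chi-square of 2.79 per degree of freedom, and those of batch 4 by 23.3. The count of 0 rests on the deficient batch 3 library: without it, the deficient batch 4 library alone against the 2 replete libraries gave 497 genes in edgeR, 149 higher and 348 lower. That batch 4 library stands apart, with 3.52% of its mapped reads in genes, the highest of the 18 libraries. Leaving out the same deficient batch 3 library gave 0 genes in edgeR where batch 1 was grouped by the genes it lists, with 707 at an unadjusted p under 0.05. With batch 1 grouped by the genes it lists, 3 libraries stood against 3, and 0 of 2658 genes passed (edgeR), with 113 at an unadjusted p under 0.05 and 0 called by DESeq2. In that grouping the log2 fold changes of batches 1 and 4 went together (Spearman 0.56 across 4022 genes), whereas those of batch 3 were unrelated to batch 1 (0.0020) and to batch 4 (0.046). These are correlations across genes, which are not independent replicates.

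**Figure D2:**
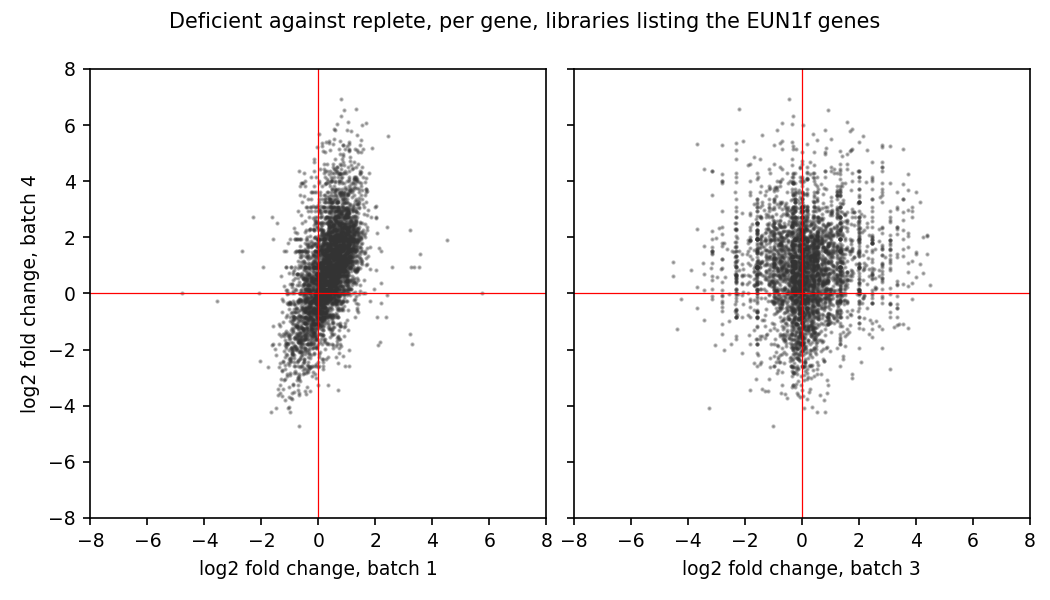
Log2 fold change of deficient against replete cultures for each of 4022 genes in the libraries that list EUN1f genes, with batch 4 on the vertical axis against batch 1 (left) and batch 3 (right). Each point is 1 gene with a mean of at least 10 reads, and red lines mark 0. Batches 1 and 4 lie along a common slope (Spearman 0.56), and batches 3 and 4 form a cloud with none (0.046).

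In EuI1c, again with 2 replete and 2 deficient libraries, no gene passed among 4271 tested (edgeR quasi-likelihood, smallest adjusted p = 1.00). There were 125 genes at an unadjusted p under 0.05, where chance gives 214, and DESeq2 and limma-voom called 0. FraEuI1c_6440 had the smallest p. This gene, at 7898906 to 7903861 on the plus strand of the chromosome, had 2 reads in the replete and 114 in the deficient libraries, a ratio of read rates of 41.8 (exact 95% interval 11.3 to 350). The batches were unlike, with 2 replete and 12 deficient reads in batch 3 and 0 and 102 in batch 4. FraEuI1c_6005 (7389850 to 7390956, plus strand) had no read in the replete libraries and 8 and 44 reads in the deficient libraries of batches 3 and 4. Set against a floor of 3 reads over the replete group, it was at least 12.7-fold higher in deficient cultures, a pooled bound carried mainly by the 44 reads of batch 4. FraEuI1c_2380 (2927457 to 2927711, plus strand) was at 280 ± 5.26 CPM in replete and 68.4 ± 1.12 CPM in deficient cultures (SD, n = 2), a log2 fold change of -2.02 (SE 0.51). FraEuI1c_2179 (2670133 to 2670726, plus strand) was at 375 ± 5.85 and 121 ± 52.4 CPM (SD, n = 2), a log2 fold change of -1.67 (SE 0.51). In batches 3 and 4, FraEuI1c_2380 had 56 and 18 replete and 9 and 19 deficient reads. FraEuI1c_2179 had 75 and 24 replete and 21 and 23 deficient reads. Counting error on so few reads is larger than both SDs of FraEuI1c_2380 and the replete SD of FraEuI1c_2179. All 4 genes kept 1 direction in both batches, and none passed (edgeR adjusted p = 1.00 for each). With no filter on low counts, FraEuI1c_6440 was called (edgeR adjusted p = 0.00096).

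Without the deficient batch 3 library of EuI1c, 15 genes passed in edgeR, 12 higher and 3 lower in the deficient batch 4 library that remained, with FraEuI1c_6440 and FraEuI1c_6005 among the higher. With batch 1 grouped by the genes it lists, 0 of 5367 genes passed (edgeR), 18 had an unadjusted p under 0.05, and DESeq2 called 0. FraEuI1c_6440 then had a log2 fold change of 1.22, FraEuI1c_6005 one of 0.43, FraEuI1c_2380 one of -1.33 and FraEuI1c_2179 one of -1.51. Without the replete batch 3 library as well, FraEuI1c_2380 was at -0.94. The smaller values of FraEuI1c_6440 and FraEuI1c_6005 came from the replete batch 1 library: without it FraEuI1c_6440 was at 4.79, with 2 replete reads left, and FraEuI1c_6005 had no replete read. Fold changes of batches 1 and 4 were inversely related in this gene set (Spearman -0.20 across 5648 genes), and those of batches 3 and 4 correlated at 0.063 across single genes and at 0.33 over 354 windows of 20 genes.

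Of the 20 most-read genes, 18 were shared by both conditions in EUN1f and 17 in EuI1c. Log2 fold changes of the genes in either list reached 1.49 in size in EUN1f and 1.47 in EuI1c. The share of reads held by the most-read genes moved differently in each batch. The most-read 1% of EUN1f genes held 39.6% (replete) and 38.0% (deficient) of the reads in genes in batch 3, and 32.7% and 13.7% in batch 4. In EuI1c they held 25.3% and 23.7% in batch 3, and 21.0% and 13.7% in batch 4. The batch 1 pair that lists EUN1f genes had 32.2% (replete) and 20.8% (deficient), and the pair that lists EuI1c genes 10.5% and 13.4%. Without the deficient batch 3 library of EUN1f, the most-read gene of each condition was lower in the 1 deficient library left. Its log2 fold change was -3.55 for the replete and -4.42 for the deficient list. With all EUN1f libraries that list EUN1f genes, 0 of the 22 genes in either list had an unadjusted p under 0.05 (edgeR). Whether the response to nitrogen deficiency differs between the strains was not tested gene by gene, because the files hold no symbol or product by which genes of different strains could be matched.

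Listed genes took 0.120% to 3.52% of the mapped reads of a library (widest Wilson 95% half-width 0.0144 percentage points), and the remaining 96.5% to 99.9% lay outside them. In EAN1pec the share was 0.377% ± 0.30 in replete and 0.283% ± 0.279 in deficient cultures (SD, n = 3), lower in the deficient library of 3 of 3 batches. In the libraries labelled EuI1c it was 0.946% ± 0.428 in replete and 1.67% ± 0.374 in deficient cultures (SD, n = 3), higher in 3 of 3 batches. In the libraries labelled EUN1f it was 1.12% ± 0.710 and 2.07% ± 1.32 (SD, n = 3), with 1 of 3 batches higher in the deficient library. The means for EuI1c and EUN1f include batch 1 libraries that list the other strain's genes, so each mixes shares over different gene sets. With batch 1 grouped by the genes it lists, the share was higher in the deficient library of 2 of 3 batches in either gene set. Two-sided exact permutation tests by label, which ignored the batch pairs, gave p = 0.5 in EAN1pec, 0.2 in EuI1c and 0.5 in EUN1f. The smallest p that 3 against 3 can give is 0.1. These tests set the group means against the spread between batches and do not test the change within batches.

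**Figure D3:**
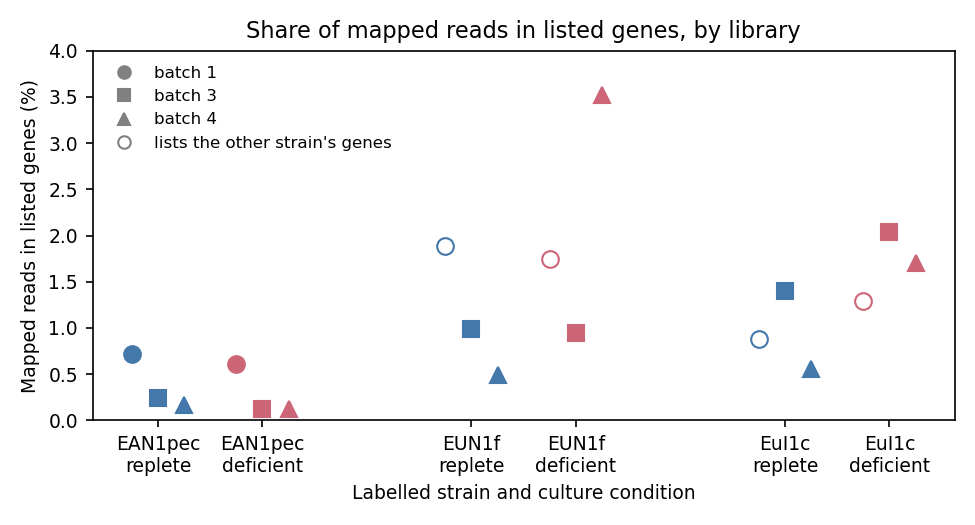
Percentage of mapped reads that fell in listed genes (vertical axis) for each of the 18 libraries, by labelled strain and condition (replete blue, deficient red). Circles are batch 1, squares batch 3 and triangles batch 4, and open circles mark the 4 libraries that list the other strain's genes. EAN1pec spans 0.120% to 0.720%, its batch 1 libraries lie above the replete batch 4 libraries of the other strains (0.486% and 0.553%), and the deficient batch 4 library of EUN1f highest, at 3.52%.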

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

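The share of mapped reads in listed genes moved in opposite directions in 2 strains. It was lower in the deficient library of all 3 batches of EAN1pec (0.842, 0.493 and 0.748 times the replete share in batches 1, 3 and 4) and higher in all 3 batches labelled EuI1c (1.46, 1.45 and 3.08 times). The mean log2 ratio of EAN1pec minus that of EuI1c was -1.46 (two-sided exact permutation test, p = 0.1, the smallest p that 3 pairs against 3 can give, 0.15 after Benjamini-Hochberg adjustment over 3 strain pairs). The labels of batch 1 bear on this difference. With batch 1 grouped by the genes it lists, a grouping chosen for this value after the result was seen, the share was higher in the deficient library of 2 of 3 EuI1c batches, and the difference was -1.24 (exact p = 0.1). EAN1pec minus EUN1f gave -1.45 by label (two-sided exact permutation test, p = 0.1, 0.15 adjusted), with 1 of 3 EUN1f batches higher in the deficient library. With batch 1 grouped by the genes it lists, that difference was -1.67 (exact p = 0.1), with 2 of 3 EUN1f batches higher. The mean difference is thus of similar size for EUN1f, but by label it rests there on batch 4. The deficient share of EUN1f was 0.923, 0.954 and 7.25 times the replete share in batches 1, 3 and 4. These values are given without an explanation.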

How the results depend on the processing

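The rise of Franean1_6204 kept its direction under all 16 alternatives run for it and passed under 14. The EAN1pec count of 1 was 2 with DESeq2 (adding Franean1_1769), with limma-voom (adding the gene beside Franean1_6204) and with no filter on low counts. The gene added with no filter, at 4542661 to 4544781, had 2341 reads in the deficient batch 1 library and 0 to 9 in each other library. The count ranged from 0 (without the replete batch 3 library) to 2 (without the deficient batch 4 library) when single libraries were left out. Settings chosen after seeing the data gave 0 without both batch 3 libraries, where Franean1_6204 had a log2 fold change of 3.80 and an edgeR adjusted p of 0.141, and 1 with reads summed over runs of neighbouring genes, with or without a block. The batch block (pairing) gave 4 in EAN1pec, 1 in EUN1f and 0 in EuI1c. In EUN1f a filter of at least 10 counts gave 1 (FrEUN1f_6880), summed runs 0 with or without a block, and leaving out single libraries 0 to 497, the highest without the deficient batch 3 library. Added for EUN1f after seeing the data, batch 1 grouped by the genes it lists gave 8 with no filter, 0 with each library left out in turn, and, without both batch 3 libraries, 0 of 4339 genes with no block and 108 (18 higher, 90 lower) with one. In EuI1c no filter gave 3 (FraEuI1c_6440 among them), leaving out single libraries 0 to 15, the highest without the deficient batch 3 library, and summed runs, chosen after seeing the data, 0 with no block and 2 with one. FraEuI1c_6005 reversed to -0.12 on the log2 scale with batch 1 grouped by the genes it lists and without the replete batch 3 library, where grouping batch 1 alone gave 0.43. The cause of the other shifts was not tested. Fewer libraries, a lone deficient library assumed to vary like the replete ones, or other genes tested are part of each left-out setting. Settings fixed beforehand for stable RNA, for tables holding RPKM alone, for gene lists and for strain differences were not run: no row is identifiable as stable RNA, counts were at hand, and gene names were not. Depth limits the shallowest EAN1pec library most, where 2007 of 7191 genes had a read.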

Other observations

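All regions, splits and tests below were chosen after the result was seen, except the 2 tests on the deficient batch 4 library of EuI1c, whose bounds were set before their values were known. In the libraries that list EUN1f genes, stretches of neighbouring genes moved together in batches 1 and 4. On the sequence called unknown, 3 windows of 20 genes at 6587304 to 6608919, 6609092 to 6623851 and 6637519 to 6660780 were lower in the deficient libraries, by log2 -0.80, -0.88 and -0.92 in batch 1 and -1.89, -2.14 and -1.55 in batch 4. In batch 3 they stood at 0.52, -0.12 and -0.13. These genes were heavily read: the last window held 41542 reads in the replete and 13056 in the deficient library of batch 1. On Contig463, a window of 20 genes at 795917 to 819243 was higher by 1.92 in batch 1 and 1.80 in batch 4, and by 0.29 in batch 3. Over 358 such windows the fold changes of batches 1 and 4 correlated at 0.84 (Spearman), and those of batches 3 and 4 at 0.016. In the libraries that list EuI1c genes the same correlation of batches 1 and 4 was -0.71 over 354 windows, and that of batches 3 and 4 was 0.33.

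In EAN1pec a gene at 4542661 to 4544781 held 2341 reads (14551 CPM of all reads in genes) in the deficient batch 1 library and 0 to 9 reads in each of the other 5 libraries. It is the only gene of the 3 gene sets with at least 200 reads in 1 library and over 20 times the rate of each other library, with 3 reads added to those. In EuI1c, FraEuI1c_6440 opens a run of 3 genes on the plus strand at 7898906 to 7904431. The summed reads of the run had a log2 fold change of 3.60 (SE 0.85) in deficient against replete cultures, with an edgeR adjusted p of 0.998 and, with a replicate block, of 0.0409. In EAN1pec, Franean1_6204 and the gene that overlaps its end gave 3.27 (SE 0.48) when summed, with an edgeR adjusted p of 0.0262.

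The 4 batch 1 files labelled EUN1f or EuI1c list the genes of the other strain. Reads of the labelled strain mapped to the wrong genome would reach fewer genes, yet at equal depth the lowest of these libraries detected 113% as many genes as the mean of batches 3 and 4 with the same gene set, which argues against that explanation. The names of these 4 files also carry the other strain. An exchange of strain labels in batch 1 stays open as a candidate explanation. The highest correlation of read counts across genes between batch 1 and the later batches was 0.894 in the EUN1f and 0.854 in the EuI1c gene set. Among the later batches the highest was 0.847 and 0.850. The lowest correlation of read counts across genes between batch 1 and the later batches, set against the lowest among the later batches, was 0.814 against 0.815 in the EUN1f gene set and 0.626 against 0.717 in the EuI1c gene set, a difference of -0.0908 that does not decide. No biological explanation was tested.

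In the EUN1f gene set, batches 1 and 4 shared their fold changes and batch 3 did not. Depth is argued against, since batch 1 thinned to the depth of batch 3 still correlated with batch 4 at 0.416 (20 thinnings, 0.400 to 0.433, against 0.556 unthinned). A trend with read density, as an even background would give, is argued against as the whole cause. The correlation was 0.432 with the median of 50 density classes taken off, where density came from batch 3. With density from all 6 libraries it was 0.465. Both lie under 0.556, so such a trend may still be part of the pattern. Whether the library labelled deficient in batch 3 has the profile of a replete one stays open: its read counts correlated at 0.847 with the replete library of batch 3, 0.842 with that of batch 4 and 0.847 with the deficient library of batch 4 (lower replete value minus deficient, -0.00573). A response to nitrogen deficiency in batches 1 and 4, the biological explanation that the design gives, stays open too, as does a batch 3 culture that did not respond.

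In the EuI1c gene set, the deficient batch 4 library resembled both batch 1 libraries: setting these 3 against the other 3 called 1301 genes in edgeR, 727 higher and 574 lower. Depth of the listed genes is argued against, since after thinning all 6 libraries to 64785 reads the split still called 37.4% as many (486 genes). An even background, such as DNA reads, is argued against as the whole cause. Of the 727 higher genes, 152 (20.9%) rose beyond what the 10th percentile of window densities allows by over 2 standard errors. The higher genes were called on these same counts, so their rises may be inflated. The changes fell with read density (Spearman -0.559 across genes), so such a background may still be part of the pattern. A difference between cultures or batches stays open and was not tested.

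With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In EAN1pec the real split called 1 gene. Counting it, 2 of 10 splits called as many, and the highest other count was 1. Among the 4 splits that part every batch pair the highest other count was 0. With batch 1 grouped by the genes listed, counts at an unadjusted p under 0.05 were compared, since the real splits called 0 genes. In the EUN1f gene set 4 of 10 splits, counting the real one, reached its 113, and the highest other was 709. In the EuI1c gene set 8 of 10, counting the real one, reached its 18, and the highest other was 2026. Both highest splits set the batch 1 pair and the deficient batch 4 library against the rest, and called 70 and 1301 genes after adjustment. This points to a structure of the libraries other than the culture condition. In both gene sets these were also the libraries with the most reads in genes. The lowest of them held 222936 reads in the EUN1f gene set, against at most 137655 in the rest. In the EuI1c gene set these values were 264745 and 240433. Depth was tested by thinning for the EuI1c split alone, so it stays open for the EUN1f split. Among the splits that part every batch pair, the highest other was 163 in the EUN1f and 21 in the EuI1c gene set.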
